A study of Mus musculus with 6 samples.

How the data were processed

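RNA was sequenced from 6 libraries of wild-type mouse intestinal organoids, 3 control and 3 exposed to 100 µM tyramine for 16 h. Per the labels' protocols, 2 µg of total RNA per library entered a stranded mRNA kit that tags cDNA with random molecular identifiers of 8 bases before amplification, and libraries were read as paired ends of 150 bases on a DNBSEQ-T7. The submitters' processing notes name STAR 2.5.3a, a read aligner, and the genome build mm10. The counting program, the annotation, the strand setting, the filters and whether reads or molecular identifiers were counted are not given in the sources used here. The deposited table holds raw counts per gene symbol, one column per library, with whole numbers whose totals differ between libraries. Column names match the sample titles, which give group and replicate number.

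Values of 1 to 8 counts were even numbers in 72.6% to 78.7% of cases per library, and whether identifiers were counted is not given, so counts are not taken as independent molecules, and the counting intervals and floors given cover counting error only. Antisense and overlapping genes, and near-identical copies such as Gsta1 with Gm3776, Krt6a with Krt6b and Hspa1a with Hspa1b, are uncertain because the counting rule is not given. The table holds 26 gene names that read as dates and 2 duplicated names; these stayed in the fit as separate rows and none is named. Gene positions are those of GENCODE M21 on GRCm38, matched by symbol, and describe whole protein-coding genes.

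From the counts, genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12139, and scaled by TMM factors of 0.962 to 1.04. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with robust estimation and group as the only term, on all 6 libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Printed CPM are counts scaled to library size times its TMM factor, as mean ± SD with n = 3 per group, log2 fold changes are tyramine minus control, and the SE is the log2 fold change divided by the square root of its F statistic. A group with 0 counts in all libraries was set to the floor of 3 counts per library for a lower bound, and with 1 to 3 counts the pooled ratio was given with an exact 95% interval.

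Gene lists, 31 in number, were fixed before the data were examined, and the 28 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Of these, 13 passed, and 0 passed with an estimated correlation. List sizes given with the numbers that rose and fell are of tested genes. Other members had too few counts or were absent from the deposited counts. Camera asks whether a list's genes rank apart from other genes, and fry, an alternative, whether they move on balance one way. Named genes were also fixed by rule: Adra2a, Lgr5, Olfm4, Ascl2 and Mki67; the 12 rising and 12 falling genes with the largest log2 fold change among called genes with a mean log2 CPM of at least 2, no overlap between groups and no model or clone name; and up to 4 called members per list, smallest p first, or where none was called the member with the smallest p; some genes picked by this rule are not used here. Other genes named were chosen after their values were seen, as were the names given for counts of 5 or fewer outside that rule (Reg1, Plin2, Acly, Gsta4, Gstm3, Ephx1, Sesn1, Casp8, Ckap2, Ahrr, Il18, Ccl28, Tjp3, Cldn15, Epcam, Maoa, Car2 and Rps14).

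The scripts were tested on simulated counts for 11848 genes with the real libraries' mean levels, sizes and dispersions. For tyramine against control, the simulation recovered 14%, 38%, 62% and 78% of 50 genes changed by 1.5, 2, 4 and 8-fold, with 8 false calls among 11504 unchanged genes, and called 5 of 5 shifted lists and 0 of 15 others. Simulated genes varied independently of each other, so this does not test false list calls where the genes of a list vary together. Because the tyramine libraries scatter more, 5 further simulations gave the groups unequal scatter and no change, and 1 to 3 genes were called in each. Each simulated gene had the scatter typical of its expression level in its group. Genes that scatter more than that were not simulated, so false calls among them were not tested. Alternatives covered size factors of the DESeq2 type, library totals alone, other filters, DESeq2 1.42.0, limma-voom, robust estimation off, a fold minimum, a replicate block, each library left out, camera with an estimated correlation and fry. Added after the data were seen were group quality weights, removal of Gsta1, Gm3776 and Gm10639, halved counts, a filter at 20 CPM, and list member counts, counts by fold and lower bounds with each library left out. No library was left out of the main result. Chi-square per degree of freedom over genes was 26.8 to 35.0 within controls and 53.3 to 99.4 within tyramine. It takes each count as independent, which counts here are not taken to be. It therefore cannot tell whether replicate libraries differed by more than sampling noise.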

Results

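Gene expression was measured by RNA sequencing in mouse intestinal organoids, which are cultured epithelial structures grown from the stem cells of the gut. Wild-type organoids were broken into single cells over 10 min and then kept for 16 h with 100 µM tyramine (3 libraries) or without it (3 control libraries). Tyramine is an amine that gut bacteria form from tyrosine. The control titles name the solvent DMSO, whereas the series' design names control medium, so whether the tyramine cultures held the same solvent is not given in the sources used here. The control libraries held 29154975, 35035955 and 28316372 counts in replicates 1 to 3, and the tyramine libraries held 29176428, 32489563 and 29898545. Of 24786 gene symbols, 17057 had a count above 0 and 12139 had enough counts to be tested. Nothing in the labels says whether the replicates came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

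The comparison of tyramine with control addresses how gene expression in these organoid cultures differs after tyramine exposure. Among genes named by a rule fixed before the data were examined, those that fell most included genes of cell division and DNA repair, and those that rose most included keratins, a prostaglandin enzyme and Hmox1. Kif4, a motor protein of mitotic chromosomes, averaged 80.6 ± 9.25 CPM (counts scaled to library size, SD, n = 3) in controls. It had 0 counts in all 3 tyramine libraries, at least 794-fold lower against a floor of 3 counts per library. That bound, and the bounds and counting intervals below, hold only if each count is independent, which is not known here. Krt6a, a keratin of stressed and squamous epithelium, rose from 0.677 ± 0.535 to 425 ± 168 CPM (log2 fold change 9.22, SE 0.510, and 10.1 without control replicate 2). Hmox1, the haem-degrading enzyme heme oxygenase 1, rose from 9.40 ± 1.71 to 504 ± 126 CPM, 53.7-fold. In all, 3127 genes (25.8% of those tested) changed, 1518 rising and 1609 falling (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted); scaled to library totals alone, 1221 rose and 1803 fell. Rises of at least 2-fold numbered 595 and falls of at least 2-fold numbered 1105. Fitted changes of at least 16-fold were seen in 70 rising and 275 falling genes, and 87 of the falling genes had 0 counts in every tyramine library. Leaving out control replicate 1, 2 or 3 lowered the 3127 genes to 1995, 1977 and 2075, and the 275 to 166, 166 and 163.

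Of the 12 rising genes named by that rule, the others were Procr, Ptgs2, Bin2, Krt5, Krt6b, Il1f9, Plet1, Myo18b, Adh7 and Scn8a. Procr, the endothelial protein C receptor, went from 0.0823 ± 0.142 to 68.4 ± 11 CPM, Bin2 from 0.0439 ± 0.0760 to 13.5 ± 5.26 CPM and Myo18b from 0.0819 ± 0.0242 to 8.27 ± 1.47 CPM; these control means lay under the floor of 3 counts per library, 0.0954 CPM, so no fold is given. Ptgs2, the inducible cyclooxygenase, rose from 0.625 ± 0.582 to 195 ± 46.2 CPM (log2 fold change 8.21, SE 0.617, and 9.02 without control replicate 2). Krt5, a basal-cell keratin, rose from 0.524 ± 0.373 to 140.5 ± 25.8 CPM (log2 fold change 8.07, and 8.81 without control replicate 1) and Krt6b from 0.468 ± 0.211 to 103 ± 53.8 CPM. Il1f9, which encodes interleukin-36 gamma, rose from 0.281 ± 0.486 to 41.8 ± 9.86 CPM, and Plet1 from 0.253 ± 0.351 to 34.7 ± 11.3 CPM; all 24 control counts of Il1f9 were in replicate 3, and 24 of the 27 of Plet1 were in replicate 2. The log2 fold changes of Adh7 and Scn8a were 5.84 and 5.69, and without control replicate 3 that of Adh7 was 7.52. The edgeR adjusted p-values of these rising genes ran from 2.2e-07 for Hmox1 to 0.0013 for Il1f9. Krt6a and Krt6b are near-identical, so the split of counts between them is uncertain.

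Among the other falling genes named by that rule, those with 0 counts in every tyramine library included Knl1, a kinetochore scaffold (at least 421-fold lower), Polq, DNA polymerase theta (at least 285-fold lower), the mitotic kinase gene Pbk (at least 187-fold lower) and Dscc1, part of a replication clamp loader (at least 148-fold lower). Proz, Rad54l and Slc6a19 were at least 133-fold, 130-fold and 113-fold lower; Rad54l acts in homologous recombination and Slc6a19 is the brush-border carrier of neutral amino acids. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, had 3 counts in the tyramine group, all in replicate 3, a pooled ratio of 3419 (95% counting interval 1170 to 16582). Cdca3, Shcbp1 and Rad51ap1 had 2 counts each in the tyramine group, in replicates 2, 2 and 1, with pooled ratios of 2718 (752 to 22451), 1731 (479 to 14299) and 1712 (474 to 14145). The edgeR adjusted p-values of these 12 falling genes ran from 2.3e-07 for Ube2c to 0.00011 for Slc6a19.

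**Figure D1:**
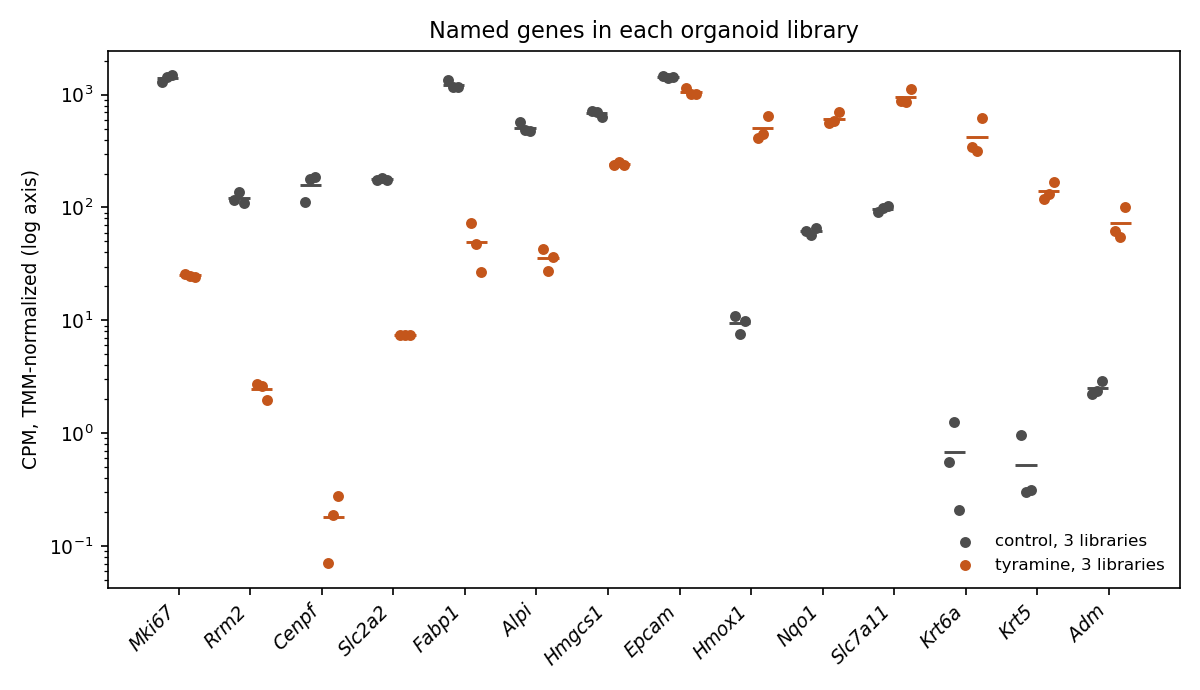
Expression of 14 genes in each library, in CPM after TMM normalization on a log axis, with a point per library and a bar at the mean of 3. Mki67 lies near 1398 CPM in controls and 25 CPM with tyramine, Hmox1 near 9.40 and 504 CPM, and no control library overlaps a tyramine library in any of these genes.

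Genes of the cell cycle fell together. Of the 40 proliferation genes fixed before the data were examined, 0 rose, 36 fell and 4 were not past the threshold, with a median log2 fold change of -3.76. Mki67, a marker of cycling cells (GRCm38 chromosome 7, 135689784 to 135716361, minus strand), fell from 1398 ± 106 to 25 ± 0.881 CPM, 55.9-fold (log2 fold change -5.81, SE 0.109; edgeR adjusted p = 2.4e-09). Rrm2, a subunit of ribonucleotide reductase, fell 49.3-fold, and Cenpf, a kinetochore protein, fell from 158 ± 40.1 to 0.179 ± 0.104 CPM. With p adjusted over the list alone, 36 fell and 0 rose. The list passed camera against all other genes (adjusted p = 1.55e-19), and the adjusted p = 0.0534 with an estimated correlation, not past the threshold. Leaving out each library gave 33 falling members (without control replicate 1) to 37 (without tyramine replicate 3).

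The receptor named in the series' title and the classical stem cell markers were near the limit of detection in both groups. Adra2a, the alpha-2A adrenergic receptor (chromosome 19, 54044151 to 54048982, plus strand), had 2, 0 and 2 counts in control replicates 1 to 3 and 2, 11 and 0 in tyramine replicates 1 to 3. Lgr5, a receptor that marks crypt base stem cells (chromosome 10, 115450311 to 115587780, minus strand), had 37, 17 and 2 counts in controls and 0, 2 and 10 with tyramine. Ascl2, a stem cell transcription factor (chromosome 7, 142966829 to 142969264, minus strand), had 4, 11 and 9 counts in controls and 0 in all 3 tyramine libraries, at least 2.46-fold lower. Olfm4, a secreted stem cell marker (chromosome 14, 79984081 to 80023139, plus strand), had 6, 2 and 2 counts in controls and 0 with tyramine, at least 1.06-fold lower, a bound that is lost without control replicate 1, where the control mean is under the floor. None of these 4 genes had enough counts to be tested with edgeR.

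Among the 19 testable members of the stem cell list, 0 rose, 4 fell and 15 were not past the threshold. Prom1, a membrane glycoprotein of progenitors, fell 2.20-fold (log2 fold change -1.14, SE 0.158; edgeR adjusted p = 0.00063). Cdca7 (log2 fold change -1.62, and -2.37 without tyramine replicate 1), Rnf43 (-0.64) and Hopx (-1.14) also fell, but 2 members fell without control replicate 1 and 1 without control replicate 2 or 3. Adjusted over the list alone 4 fell, and the list as a whole did not pass camera (adjusted p = 0.0979, and adjusted p = 0.213 with an estimated correlation), although it did with no filter on low counts (camera adjusted p = 0.0252) and by fry, which asks another question (adjusted p = 0.0016); camera gave 0.0252 to 0.213 over its alternatives. Of 12 Wnt targets, Ephb2 and Rnf43 fell and Ephb3 rose (log2 fold changes -1.25, -0.64 and 2.47) and 9 were not past the threshold, against 3 falling and 1 rising adjusted over the list alone; the camera adjusted p = 0.564, and adjusted p = 0.653 with an estimated correlation. Of 7 Notch pathway genes, the ligand gene Dll1 fell 4.17-fold, Notch2 rose 2.43-fold and 5 were not past the threshold, against 2 falling and 1 rising adjusted over the list alone; the camera adjusted p = 0.613, and adjusted p = 0.655 with an estimated correlation. Ephb3 and Notch2 lost their calls when any control library was left out, and Ephb3 also without tyramine replicate 3 (log2 fold change 1.74). Rnf43 lost its call without control replicate 2 or 3, and 2 Notch pathway genes fell without tyramine replicate 1 or 2. The 12 Wnt targets and 7 Notch pathway genes are those tested, from fixed lists of 21 and 14.

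Genes of mature absorptive cells fell. In the enterocyte list, 30 of 39 tested members fell, 8 were not past the threshold and Reg1 rose (log2 fold change 1.28), with a median log2 fold change of -2.35. Slc2a2, the glucose transporter GLUT2 (chromosome 3, 28697903 to 28731359, plus strand), fell 24.0-fold from 178 ± 5.39 to 7.41 ± 0.0711 CPM (edgeR adjusted p = 1.2e-07). Slc5a1, the sodium-glucose cotransporter, fell 13.3-fold and Alpi, intestinal alkaline phosphatase, fell 14.3-fold. When p was adjusted over the list alone, 31 fell and 1 rose, and the list passed camera (adjusted p = 3.03e-15, and adjusted p = 0.0759 with an estimated correlation). Reg1, singled out after its value was seen, was not past the threshold without any 1 control library or tyramine replicate 2.

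Of 17 enteroendocrine genes, 7 fell, 0 rose and 10 were not past the threshold; Chgb, a granule protein of hormone-secreting cells, fell 2.66-fold from 904 ± 35 to 339.8 ± 95.9 CPM. Gip, a hormone gene, fell 19.3-fold (log2 fold change -4.27, and -5.21 without tyramine replicate 2), and Tph1, which starts serotonin synthesis, was at 0 counts in all tyramine libraries, at least 33.1-fold lower. Gip was not past the threshold with limma-voom and group weights, a setting added after the data were seen (adjusted p = 0.0641). With p adjusted over the list alone 8 fell, and the list passed camera (adjusted p = 0.000511, and adjusted p = 0.0759 with an estimated correlation). Of 15 goblet cell genes, 2 rose, 6 fell and 7 were not past the threshold, with the same 2 and 6 adjusted over the list alone; Clca3b rose 7.20-fold, Galnt3 rose 1.83-fold and Tspan13 fell 2.88-fold. The goblet list did not pass camera (adjusted p = 0.109, and adjusted p = 0.224 with an estimated correlation), and the number that fell was 1 without control replicate 1, and 2 without control replicate 2, control replicate 3 or tyramine replicate 1. Among 13 Paneth cell genes, Pnliprp2 fell 2.30-fold, the antimicrobial gene Ang4 was at 0 in the tyramine libraries (at least 10.4-fold lower, and at least 5.75-fold without control replicate 1) and Cd24a rose 1.48-fold, while 10 were not past the threshold, with 2 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.327, and adjusted p = 0.655 with an estimated correlation). Cd24a was also the only one of 6 tested tuft cell genes past the threshold, with 0 adjusted over the list alone. For the tuft list the camera adjusted p = 0.327, and adjusted p = 0.516 with an estimated correlation. The fixed Paneth and tuft lists held 30 and 28 genes, so most of their members were not tested. Ang4 lost its call without any 1 control library, and Cd24a without any 1 library except tyramine replicate 3.

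Lipid genes fell in both the synthetic and the oxidative lists. Of 25 cholesterol synthesis genes, 21 fell, 0 rose and 4 were not past the threshold, with a median log2 fold change of -1.35. Hmgcs1, which makes the precursor of mevalonate (chromosome 13, 119690379 to 119708260, plus strand), fell 2.81-fold from 683 ± 47.7 to 243 ± 8.14 CPM, Mvd fell 4.77-fold and Insig1 3.72-fold. Adjusted over the list alone 22 fell (camera adjusted p = 2.61e-09, and adjusted p = 0.102 with an estimated correlation). Of 28 genes of fatty acid oxidation and its regulator PPAR, 20 fell, 7 were not past the threshold and Plin2, a lipid droplet coat gene, rose (log2 fold change 0.54). Fabp1 and Fabp2, fatty acid binding proteins that are also in the enterocyte list, fell 24.9-fold and 4.58-fold, Acaa2 fell 4.68-fold and Ucp2 fell 4.87-fold. Adjusted over that list alone 21 fell and 2 rose (camera adjusted p = 5.89e-08, and adjusted p = 0.0759 with an estimated correlation). Plin2, singled out after its value was seen, lost its call without control replicate 1 or 3.

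Among 15 fatty acid synthesis genes, 7 fell, 6 were not past the threshold, and Acly and Me1 rose. The desaturase gene Scd1 fell 8.49-fold, Scd2 8.06-fold and Elovl5, an elongase gene, 4.55-fold, whereas Me1, malic enzyme 1, which the NRF2 list also holds, rose 2.02-fold. When p was adjusted over the list alone 7 fell and 2 rose (camera adjusted p = 0.0243, and adjusted p = 0.348 with an estimated correlation); the list also missed the threshold without tyramine replicate 2 (camera adjusted p = 0.0580) or with the filter at 20 CPM (0.0800), within a camera range of 0.00645 to 0.348 over its alternatives, and the rising count was 1 without any 1 library but tyramine replicate 1. Of 33 nuclear genes of oxidative phosphorylation, 17 fell, 0 rose and 16 were not past the threshold, with a median log2 fold change of -0.58. Sdha, a subunit of succinate dehydrogenase, fell 2.02-fold, Atp5a1 1.69-fold and Uqcrc1 1.67-fold. With p adjusted over the list alone 18 fell (camera adjusted p = 5.56e-06, and adjusted p = 0.185 with an estimated correlation). Of 29 glycolysis and hypoxia genes, 11 rose, 8 fell and 10 were not past the threshold. Adm, adrenomedullin, rose 28.9-fold and Ero1l 3.54-fold, while Car9, a carbonic anhydrase, fell 7.52-fold and Pfkp, a phosphofructokinase gene, fell 2.17-fold. Adjusted over the list alone 11 rose and 9 fell, with a median log2 fold change of -0.04 where the test and the mean pointed upward (camera adjusted p = 0.642, and adjusted p = 0.798 with an estimated correlation); 5 fell without any 1 control library.

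Targets of NRF2, the transcription factor of the oxidative stress response, rose. In this list 24 of 30 tested genes rose, 3 were not past the threshold and Gsta4, Gstm3 and Ephx1 fell, with a median log2 fold change of 1.52. Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403206, minus strand), rose 9.98-fold from 61.4 ± 4.03 to 613 ± 76.5 CPM (edgeR adjusted p = 2e-07). Slc7a11, the cystine transporter, rose 9.77-fold from 97.4 ± 6.01 to 951 ± 142 CPM, and Gsta2, a glutathione S-transferase gene, rose 6.99-fold. When p was adjusted over the list alone, 25 rose and 3 fell, and the list passed camera (adjusted p = 7.84e-13, and adjusted p = 0.0534 with an estimated correlation). Gsta1 and its near-identical copy Gm3776 together took 4.99% to 5.46% of all counts in controls and 7.25% to 9.29% in the tyramine libraries, and values of single glutathione S-transferase genes are uncertain.

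**Figure D2:**
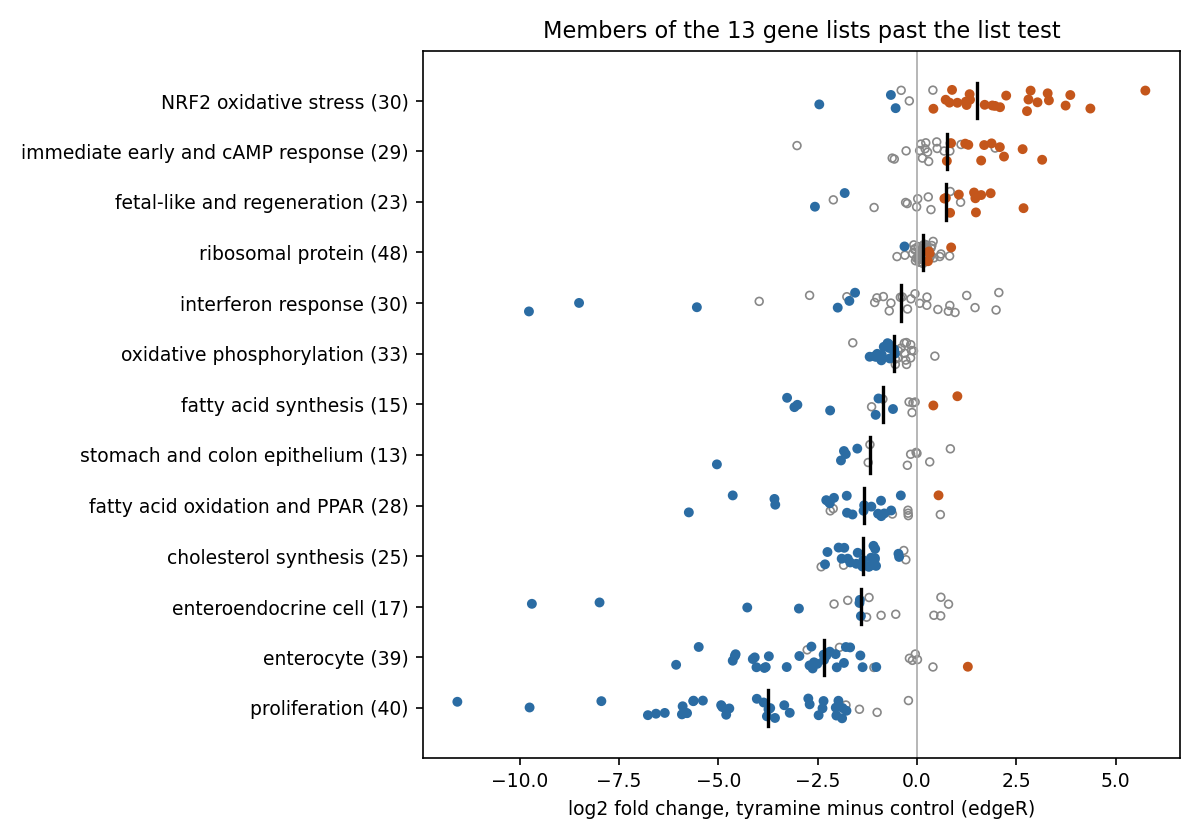
Log2 fold change, tyramine minus control, of each tested member of the 13 lists past the camera test, with the number tested in parentheses. Filled orange points rose, filled blue points fell, open points were not past the threshold, and black bars are list medians; the proliferation median is -3.76 and the NRF2 median 1.52. Fitted values of genes at 0 counts in the tyramine libraries depend on the prior count.

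Other stress lists held members that moved both ways. Of 31 genes of the unfolded protein and integrated stress responses, 9 rose, 9 fell and 13 were not past the threshold, with 10 and 10 adjusted over the list alone. Ppp1r15a, a phosphatase subunit induced by stress, rose 12.3-fold and Slc3a2, the partner of Slc7a11, rose 4.2-fold, while the chaperone gene Hsp90b1 fell 1.65-fold. The camera adjusted p = 0.613, and adjusted p = 0.841 with an estimated correlation; 6 fell without control replicate 2 or 3, and 6 rose without control replicate 3. Of 29 p53 and apoptosis genes, 6 rose, 18 were not past the threshold and 5 fell, among them Sesn1, Casp8 and Ckap2. Cdkn1a, the cell cycle inhibitor p21, rose 3.14-fold from 36.9 ± 9.11 to 116 ± 7.52 CPM, Pmaip1 1.85-fold and Ccng1 1.52-fold. With p adjusted over the list alone 9 rose and 5 fell (camera adjusted p = 0.0648, and adjusted p = 0.224 with an estimated correlation). The p53 list passed without tyramine replicate 2 (camera adjusted p = 0.0430), with no filter on low counts (0.0380) and with group weights (0.0324), within a camera range of 0.0324 to 0.224 over its alternatives. Its falling count was 3 without any 1 control library. Of 10 aryl hydrocarbon receptor genes, Ahrr, Tiparp and Nqo1 rose, Ugt1a6a and Il22ra1 fell and 5 were not past the threshold, against 4 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.139, and adjusted p = 0.516 with an estimated correlation).

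Immediate early and cAMP response genes rose, 11 of 29 tested, with 0 falling and 18 not past the threshold. Fosl1, an AP-1 transcription factor gene, rose 8.87-fold from 38.4 ± 9.57 to 340.4 ± 86.3 CPM, Dusp4 rose 4.56-fold and Nr4a2 3.67-fold. Areg, the growth factor amphiregulin, rose 3.06-fold from 297 ± 12.1 to 910.0 ± 44.3 CPM. Adjusted over the list alone 11 rose (camera adjusted p = 9.75e-05, and adjusted p = 0.0759 with an estimated correlation), and 7 rose without control replicate 3, while 1 fell without control replicate 3, tyramine replicate 1 or tyramine replicate 3 and 2 fell without tyramine replicate 2. In the fetal-like and regeneration list, which also holds Areg, 10 of 23 rose, 11 were not past the threshold, and Il1rn and Msln fell 3.53-fold and 5.93-fold. Cldn4, a tight junction claudin, rose 2.77-fold. When p was adjusted over the list alone 11 rose and 2 fell (camera adjusted p = 0.00982, and adjusted p = 0.102 with an estimated correlation).

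Inflammatory genes moved in both directions. From a fixed list of 35 NF-kB and inflammatory genes, 16 had enough counts to be tested. Of 16 NF-kB and inflammatory genes, Ptgs2, Cxcl16 and Tnfaip3 rose, Pigr, Il18 and Ccl28 fell and 10 were not past the threshold, the same numbers as adjusted over the list alone. Pigr, the carrier of secretory immunoglobulin, fell 11-fold from 516 ± 2.72 to 46.8 ± 11.5 CPM. The camera adjusted p = 0.716, and adjusted p = 0.798 with an estimated correlation; 1 rose without control replicate 1, Tnfaip3 also lost its call without control replicate 2, and 1 fell without any 1 control library. Of 30 interferon response genes, 6 fell, 0 rose and 24 were not past the threshold, with 6 falling adjusted over the list alone. Ifi27l2b fell 2.95-fold, and Psmb9, an immunoproteasome subunit gene, was at 0 in the tyramine libraries, at least 34.8-fold lower. The list passed camera (adjusted p = 0.0133, and adjusted p = 0.102 with an estimated correlation), 4 fell without control replicate 1 or 3, and 1 rose without tyramine replicate 1.

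Of 21 tight junction and barrier genes, 6 rose, 10 were not past the threshold, and Tjp3, Cldn2, Cldn15, Epcam and Muc13 fell, the same numbers as adjusted over the list alone. Ocln, occludin, rose 1.93-fold, Cldn2, a pore-forming claudin, fell 2.51-fold and the transmembrane mucin gene Muc13 fell 2.34-fold (camera adjusted p = 0.407, and adjusted p = 0.516 with an estimated correlation). Among 14 amine receptor and amine metabolism genes, Maob, Aoc1, Slc6a4 and Sult1d1 fell, 2 rose, among them Maoa, and 8 were not past the threshold, the same numbers as adjusted over the list alone. Maob, monoamine oxidase B, fell 32.6-fold from 48.6 ± 3.34 to 1.47 ± 2.09 CPM (log2 fold change -5.03, and -7.50 without tyramine replicate 2), whereas Maoa, monoamine oxidase A, rose from 427 ± 46.0 to 553 ± 27.6 CPM (log2 fold change 0.37, SE 0.101; edgeR adjusted p = 0.022). Sult1d1, a sulfotransferase gene, fell 2.94-fold, and Slc6a4, the serotonin transporter, was at 0 with tyramine, at least 37.1-fold lower. Aoc1, diamine oxidase, had 183 counts in the controls and 2 with tyramine, both in replicate 3. The camera adjusted p = 0.276, and adjusted p = 0.446 with an estimated correlation. The rising count was 0 without control replicate 1, control replicate 2 or tyramine replicate 2, and 1 without control replicate 3 or tyramine replicate 1, and Aoc1 lost its call without any 1 control library or tyramine replicate 2. Adra2b and Taar1, other receptor genes for tyramine-like amines, had 0 counts in all 6 libraries, and Adra2c had 2 counts in tyramine replicate 2 and 0 elsewhere. Maoa, Adra2b, Adra2c and Taar1 were named after their values were seen. The fixed amine list held 35 genes, and those beyond the 14 tested had too few counts.

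Most markers of cells other than gut epithelium had too few counts or were not past the threshold. Of 17 fibroblast and mesenchyme genes 0 rose and 0 fell, also adjusted over the list alone (edgeR; 1 at an unadjusted p under 0.05, 1 called by DESeq2 and 1 by limma-voom), and 1 fell without tyramine replicate 2. The member with the smallest p was Myh11, smooth muscle myosin, at 9.39 ± 0.283 CPM in controls and 16.5 ± 3.73 CPM with tyramine (edgeR adjusted p = 0.089, and 0.026 by DESeq2). The fibroblast median log2 fold change was -0.22 while camera pointed upward (adjusted p = 0.935, and adjusted p = 0.956 with an estimated correlation). Immune cell genes had 2 testable members, neither past the threshold with edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), among them Lyz2 at 1.46 ± 0.406 and 1.66 ± 0.124 CPM. Of 4 testable endothelial and neural genes, Lyve1 fell from 3.21 ± 1.30 to 0.120 ± 0.111 CPM (log2 fold change -4.69, and -5.44 without tyramine replicate 2), a call lost without any 1 control library, and 3 were not past the threshold. Those last 2 lists were too small for a list test. The list named stomach and colon epithelium also holds intestinal genes such as Cdx2 and the ileal gene Fabp6, so it does not mark foreign cells alone. Of its 13 tested genes, Car2, Slc26a3, Cdx2, Pdx1 and Mettl7b fell, 0 rose and 8 were not past the threshold. The numbers were the same adjusted over the list alone (camera adjusted p = 0.0358, and adjusted p = 0.180 with an estimated correlation). Cdx2, which encodes an intestinal identity transcription factor, fell 3.46-fold and Slc26a3, a chloride exchanger gene, 3.77-fold. That list missed the threshold without control replicate 1 (camera adjusted p = 0.0698) or tyramine replicate 1 (0.0658), with group weights (0.0511) and with the filter at 20 CPM (0.277), within a camera range of 0.0158 to 0.277 over its alternatives, and 3 members fell without any 1 control library, with Mettl7b among those lost.

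Ribosomal protein genes shifted little. Of 48, Rpl24, Rpl19, Rplp0 and Rps14 rose, Rpl3 fell and 43 were not past the threshold, with 0 in either direction adjusted over the list alone and a median log2 fold change of 0.16. The list passed camera (adjusted p = 0.0280, and adjusted p = 0.185 with an estimated correlation), but not without control replicate 1 (0.0594), control replicate 2 (0.0767) or tyramine replicate 1 (0.0569) or with the filter at 20 CPM (0.233), within a camera range of 0.0158 to 0.233 over its alternatives, and the 4 rising became 1, 0 and 2 without control replicates 1, 2 and 3, and 1 and 2 without tyramine replicates 1 and 2. Rpl3 lost its call without control replicate 1 or 2 or tyramine replicate 1 or 2, and 2 fell without tyramine replicate 3. Of 7 replication histone genes, Hist1h2bc rose 2.30-fold and Hist1h1c 2.25-fold, also adjusted over the list alone, and 5 were not past the threshold (camera adjusted p = 0.0547, and adjusted p = 0.185 with an estimated correlation). The 13 mitochondrially encoded genes were not analysed here.

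The libraries separated by group, and the tyramine libraries differed more among themselves. The first principal component of log2 CPM held 56.6% of the variance and separated the groups, at -82.8, -80.4 and -80.6 for controls and 54.1, 69.1 and 120.6 for tyramine replicates 1 to 3. Across genes, Pearson's r was 0.954 to 0.962 between control libraries, 0.883 to 0.908 between tyramine libraries and 0.802 to 0.859 between groups; genes are not independent replicates. For genes at 10 to 20 CPM the median coefficient of variation was 21.6% in controls and 38.5% with tyramine. Of 10330 genes with 100 or more counts in a control library, 16 had 2 or fewer in another control library, against 329 of 10307 in the tyramine group. Among tested genes 44.5% had no overlap between the groups, where chance gives 10% for 3 against 3, and 3124 of the 3127 changed genes had none.

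**Figure D3:**
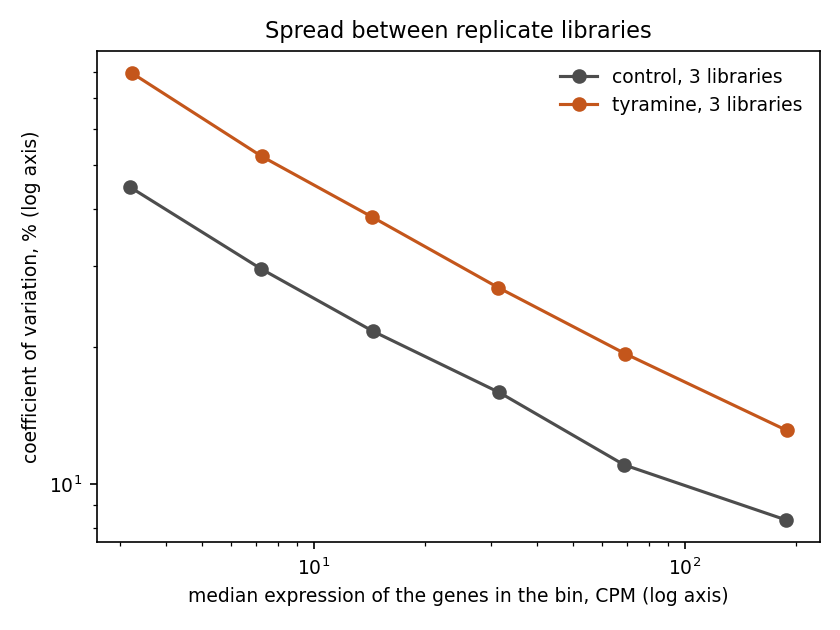
Median coefficient of variation between the 3 libraries of a group, in percent, against the median expression of the genes in each bin, in CPM, both on log axes, for control and tyramine libraries. The tyramine line lies above the control line in all 6 bins, at 38.5% against 21.6% for genes at 10 to 20 CPM.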

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

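The alternatives with group quality weights, without Gsta1, Gm3776 and Gm10639, with halved counts and at 20 CPM were chosen only after the data were seen. The number of changed genes, 3127, was between 2560 and 4087 under every other normalization, filter and tool run, and 0 of the genes called in the main fit were called in the opposite direction. With a 2-fold minimum it was 1700, of which 595 rose, by construction. Leaving out each library in turn gave 1977 to 3307 changed genes, 934 to 1510 rising and 1035 to 1797 falling; the low totals, 1977 to 2075, came without a control library, against 2933 to 3307 without a tyramine library. The 13 lists past camera became 0 with an estimated correlation between genes; the cause was not tested. Leaving out each library gave 11 to 13 lists, and fry, which does not compare a list with other genes, gave 18. The replicate numbers did not pair the samples: same-numbered libraries deviated together with r of -0.0244, -0.0239 and -0.000339, and no library correlated best with its own number. With the numbers as a replicate block, 2594 genes changed, and 1 more list, replication histone, passed (adjusted p = 0.0446).

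Of 115 genes picked by the naming rule and past the threshold, some of them not used here, all 115 kept their direction and 96 stayed past it under every alternative that tested them. Over all genes picked, 1988 gene-by-alternative results were as in the main fit, 80 were no longer past the threshold and 1 newly was (Myh11, DESeq2). Lyz2, never past the threshold, ranged from a log2 fold change of -0.029 without control replicate 3 to 0.35 without control replicate 1. Directions turned in 2 lists that never passed. The fibroblast list pointed down with no filter (adjusted p = 0.940), by fry (0.800), with group weights (0.981) and without control replicate 1 (0.668), control replicate 2 (0.926), tyramine replicate 2 (0.763) or tyramine replicate 3 (0.775); leaving out each library gave 0.665 to 0.926. The NF-kB list pointed down by fry (0.518) and without tyramine replicate 3 (0.815); leaving out each library gave 0.475 to 0.972. The cause was not tested in either. Few counts limit what can be said of the stem cell and receptor genes, and whether depth or low expression is the reason was not tested. Recovery of simulated 1.5-fold changes was 14%.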

Other observations

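The proteasome, heat shock, repair, keratin, inhibitor and synthetase gene groups were listed after other results had been seen, and the tests on matched lists, length and GC, glutathione S-transferase genes, abundant genes and replicate scatter were chosen only after the related result was seen; the tests on splits of the libraries, cell cycle inhibitors and the proteasome were written before their results were seen. Proteasome subunit genes rose together, 24 of 33 with 0 falling and a median log2 fold change of 0.59 (camera adjusted p = 1.05e-09, and adjusted p = 0.0216 with an estimated correlation); Psma5 and Psmd14 rose by 1.08 and 1.05 on the log2 scale. Of 24 heat shock and chaperone genes, 11 rose, among them Hspa1a (log2 fold change 3.36, and 2.68 without tyramine replicate 3), Hsp90aa1 (1.77) and Bag3 (1.43), and Hspd1 and Fkbp4 fell (camera adjusted p = 0.00057, and adjusted p = 0.119 with an estimated correlation). Of 18 genes of homologous recombination and Fanconi repair, 12 fell and 0 rose, with Brca1 at -3.89, but 3 of the 18 were already among the falling genes named for their size, so no test of this list is given. Of 11 squamous and wound keratin genes, Krt5, Krt6a, Krt6b, Sprr1a and Il1f9 rose and 0 fell, but 4 of these 5 were already among the rising genes named for their size, so no test is given here either, while Krt14, a partner of Krt5, was at 0.653 ± 0.240 and 0.810 ± 1.05 CPM, with 57, 10 and 3 counts in tyramine replicates 1 to 3, and Trp63 had 2 counts in control replicate 2, 12 in tyramine replicate 1 and 0 elsewhere. Of 20 aminoacyl-tRNA synthetase genes 6 rose and 4 fell (camera adjusted p = 0.310).

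Epithelial levels stayed high beside the stem cell markers near 0. Krt8 was at 6297 ± 344 CPM in controls and 6687 ± 331 with tyramine, and Krt20 at 4230.5 ± 159.5 and 4107 ± 466 CPM, neither past the threshold, whereas Epcam fell from 1434 ± 27.2 to 1054 ± 77.3 CPM. Smoc2 and Ly6a, markers of stem and fetal-like cells, varied between tyramine libraries (7, 73 and 168 counts, and 26, 110 and 249 counts in replicates 1 to 3). The ileal gene Fabp6 had 0 counts in all 6 libraries.

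The fall of proliferation genes has a list median of -3.76. Random lists of 40 genes matched on mean expression, 10000 of them, had medians no lower than -0.54. Expression level alone thus did not give a median of -3.76. This cannot tell whether the tyramine libraries held fewer independent molecules. Fewer molecules mainly add scatter, so random lists would lie near 0 either way. Random lists of genes matched on transcript length and GC content, 10000 of them, had medians no lower than -0.69, which argues against that bias as the whole cause. Induction of cyclin-dependent kinase inhibitors stays open: 1 of 6 tested inhibitor genes rose (Cdkn1a) and 1 fell (Cdkn2d). The tyramine exposure itself may be the source, and any difference in solvent or handling that goes with the groups cannot be separated from it by this design.

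The rise of NRF2 genes does not rest on near-identical glutathione S-transferase genes, since 20 of the 24 members outside that family rose. The 10 most abundant genes took 9.79% to 10.4% of counts in controls and 13% to 15% with tyramine, a difference of means of 4.0 percentage points. Scaled to library totals, this lowers rather than raises all other genes. TMM scaling offsets it, with factors of 1.01 to 1.04 in controls and 0.962 to 0.979 with tyramine. Those factors are small beside the list's median log2 fold change of 1.52, which argues against a changed share of these genes as the whole cause. A candidate explanation is a proteotoxic stress response that includes the proteasome, and 24 of 33 proteasome genes rose, as that hypothesis needs. The rise cannot decide it, since proteasome genes that rose together with NRF2 genes for another reason would look the same. The other stress lists differed. Of 24 heat shock and chaperone genes, 11 rose and 2 fell, with a median log2 fold change of 0.42. That list passed camera upward (adjusted p = 0.00057) but not with an estimated correlation (adjusted p = 0.119). Of 31 unfolded protein and integrated stress genes, 9 rose and 9 fell. The proteotoxic explanation remains a hypothesis, since it was formed and tested on the same libraries, and a direct effect of the tyramine exposure stays open.

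The wider scatter between tyramine libraries had a slope of log squared coefficient of variation on log mean of -0.885, against -0.833 in controls, close to the inverse relation that fewer independent molecules would give. Because both groups had nearly the same slope, it cannot tell fewer molecules from real differences between the tyramine cultures. If all scatter were sampling noise, counts per independent unit were 65.0 with tyramine and 20.8 in controls (medians of 5 bins from 2 to 100 CPM). At 100 to 1000 CPM they were 98.9 and 40.3. Fewer captured molecules is thus a candidate explanation, although values that rise with expression depart from a fixed number of counts per molecule. On that reading the floor of 3 counts is too low and the printed lower bounds would shrink. Tph1, with 90, 151 and 85 counts in controls, and Ang4, with 61, 17 and 20, may then have no lower bound. The same holds for Psmb9 and Slc6a4, whose printed bounds of 34.8-fold and 37.1-fold are close to the 33.1-fold of Tph1. It holds too for the smaller bounds of Ascl2 and Olfm4. Larger bounds, such as 113-fold for Slc6a19, would be far smaller. Whether tyramine replicate 3 alone stands apart cannot be settled. Tyramine replicates 1 and 2 scattered 1.19 times as much as the most scattered control pair, within the 1.2 times set as the bound for it. A second measure added after that value was seen, chi-square over all genes, gave 1.53 times. Median absolute log2 differences were 0.305 and 0.290 for the pairs with replicate 3, against 0.213 for replicates 1 and 2. The second principal component, with 19.3% of the variance, placed replicate 3 at 82.2 and replicates 1 and 2 at -37.5 and -76.6. Without tyramine replicate 3 the fit called 3307 genes, and real differences between the tyramine cultures stay open and were not tested.

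The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3127 changed genes and the highest of the others 0, so 1 of the 10 splits reached the real count. Every other split mixed control and tyramine libraries in both groups, which turns a difference between groups into spread within them. For lists the real split gave 13 and the others 3 to 7, again 1 of 10. Camera with the preset correlation thus called lists in every mixed split as well. Low counts were even in 72.6% to 78.7% of cases per library, and with all counts halved 3198 genes changed.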
